A study of Mus musculus with 3 samples.

How the data were processed

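RNA of BV-2 cells, an immortalized mouse microglial line, was measured in 3 samples: untreated cells, cells given lipopolysaccharide (LPS) for 6 h, and cells given LPS together with obovatol for 6 h. Per the labels' protocols, the cells grew at 37 °C in DMEM with 5% heat-inactivated serum and 50 µg/ml gentamicin, RNA was taken up in Trizol, and biotin-labelled cRNA was made for Illumina bead arrays. The doses of LPS and obovatol, and a time for the untreated cells, are not given in the sources used here. The software named in the submitters' processing notes is BeadStudio 3.0. The design text states 1 biological replicate per group.

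The deposited signal table holds a linear intensity for each of 45281 probe rows on 6 arrays, 2 for each sample. Per the file headers, 1 array of each sample carries the sample's own name and the other is called its replicate. The table has no detection p-values, bead errors or control probes. The medians of the intensities differ between arrays and no value lies at or below 0, so neither scaling nor background subtraction is visible in the deposited intensities. The deposited series table holds 1 log2 value per probe row and sample. Its scale and making are not stated in the labels and were worked out from the values. The log2 intensities, quantile normalized over the 6 arrays and averaged over the 2 arrays of a sample, differed from the authors' log2 values by at most 0.012. Every other pair of arrays left a largest difference of at least 1.01. No column of the tables went unused (0 columns).

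The planned analysis took detection p-values and negative controls for granted, and these are not in the signal table. In their place, the background was corrected with the normexp model fitted to the intensities alone (limma 3.58.1 in R 4.3.3) with an offset of 16. Arrays were then quantile normalized, brought to log2, and averaged over the 2 arrays of each sample. A nominal detection cut was set per array from the mode of the log2 intensities and the spread of the values below that mode, at a one-sided rate of 0.01. A sample counted as detecting a row when both of its arrays passed the cut. A comparison used the rows detected in at least 1 of its 2 samples, and a change was counted at a log2 difference of at least 1, which is 2-fold. The offset pulls differences of dim rows towards 0. The cuts lay between intensities of 47.1 and 56.4. In a stretch of 1311 adjacent rows almost without bright signal, the 99th percentile of the intensities was 63.7, so the nominal cut is lenient.

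The 2 arrays of a sample were counted as 1 replicate, since the design text gives 1 biological replicate per group. No test between groups was therefore possible and no p-value is given. For each changed row, the difference was also taken for each of the pairings of an array of 1 sample with an array of the other. This shows the spread between arrays, not between cultures. The number of arrays limits the precision.

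The probe IDs on the rows were joined to the platform's gene annotation, which gave 1 gene symbol for 34885 rows, several for 18 and none for 10378. The gene IDs of 34807 rows were found in the RefSeq gene table. The pairing of gene names with values was then checked on genes of known high expression, on gene families, and on the order of the rows. Because it failed these checks, the unit of analysis was the probe row and not the gene, and no change is assigned to a gene. Rows are named by their position in the signal table, with row 1 as the first probe row. The 31 gene lists and the panel of 18 genes that were fixed before the data were examined were used only to check the pairing. The 29 lists with at least 5 detected members were each set against 10000 random lists of the same size and similar brightness. Rows were to be named by size, as the largest increases and decreases among rows detected in both samples of a comparison. At most 2 in each direction are printed, since row positions carry no identity.

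The functions were tested on simulated data for the comparison of LPS with untreated cells. Arrays were drawn for all 45281 rows from the real means and the real differences between arrays, with known folds put into 4 sets of 50 rows. The changed rows were taken only from rows with a mean intensity well above the detection cuts, so recovery of changes in dim rows was not tested. Of 50 rows with a true 2-fold change, 32% passed the 2-fold limit, with a median log2 difference of 0.90. All 50 rows with a 3-fold change, all 50 with a 4-fold change and all 50 with an 8-fold change passed. Of 19358 unchanged rows kept by the filter, 0 passed.

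A further simulation of 100 runs drew 3 unchanged samples with the noise seen between the 2 arrays of each sample, and gave the counts that this noise alone produces. It leaves out spread between cultures and any shift shared by arrays of different samples. The alternatives were other background corrections, median scaling, the authors' log2 values, other detection filters, and thresholds of 1.5-fold and 3-fold. After the data had been examined, the first arrays alone, the second arrays alone, another brightness filter, normexp with no offset, and splits of the LPS arrays and of the untreated arrays were added.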

Results

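The series measured gene expression in BV-2 cells, a mouse microglial cell line, under 3 conditions. It set LPS, a glycolipid of the outer membrane of Gram-negative bacteria that activates Toll-like receptor 4, against no treatment. It also set LPS given with obovatol, a biphenolic compound known from Magnolia bark, against LPS alone. The title states the question, which is how obovatol affects the expression that LPS induces in microglia. The design text gives each condition 1 biological replicate, and each was measured on 2 arrays, so no difference below has a biological replicate check.

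The 6 arrays were alike in brightness. Median intensities ran from 43.5 to 52.4 and the highest from 23858 to 29100, and between 43.5% and 45.3% of the 45281 probe rows were detected on each array. Over the 20368 rows detected in at least 1 sample, the 2 LPS arrays had a Pearson correlation of 0.997 across rows, with 1 row at least 2-fold apart. The 2 untreated arrays had a correlation of 0.991 with 97 rows apart, and the 2 arrays of LPS plus obovatol 0.990 with 106 rows apart. Rows are not independent replicates. The second-minus-first differences of these 2 samples had a correlation across rows of 0.51, so their second arrays share a shift, which the LPS arrays lack and the simulation of noise below leaves out. The difference between the first arrays of untreated cells and LPS, 104 rows, was of the same size as that between the 2 untreated arrays.

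The gene names attached to the rows did not match the values on them. Beta-actin (Actb), a cytoskeletal protein with an abundant transcript in nearly all cells, was listed on 5 rows with mean intensities between 45.2 and 256, and 16.05% of all rows were brighter than the brightest of these. The row listed for the glycolytic enzyme Gapdh had a mean intensity of 37.7 and was not detected. The 3 rows listed for Eef1a1, an elongation factor of translation, reached at most 58.3. Ribosomal proteins, whose transcripts are among the most abundant of a growing cell, were listed on 89 rows, of which 52.8% were detected, with a median intensity of 51.7. Olfactory receptors, which are expressed in sensory neurons of the nose, were listed on 1287 rows, of which 47.3% were detected. Of all rows, 45.0% were detected and the median intensity was 47.3.

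Rows listed for inflammatory, antioxidant and microglial genes changed little. Of the fixed panel of 18 such genes, 11 were detected in at least 1 sample, and 0 differed 2-fold between LPS and untreated cells or between LPS plus obovatol and LPS. The row listed for Nos2, the inducible nitric oxide synthase, had intensities of 57.3 in untreated cells, 49.4 with LPS and 62.2 with LPS plus obovatol. The row listed for Tnf, a proinflammatory cytokine, had 63.1, 52.5 and 60.0 in the same order. Some panel rows were bright in all samples, with 2365, 1839 and 1861 for Ptgs2 and 575, 468 and 541 for Il6. For a gene listed on several rows, the row with the highest mean log2 value was taken. The rows listed for the cytokine Il1b, the chemokine Ccl5 and Aif1, a marker of microglia, were not detected in any sample. Of the 29 gene lists, the medians of the log2 difference between LPS and untreated cells ran from -0.15 to 0.16. Between LPS plus obovatol and LPS they ran from -0.19 to 0.19, and between LPS plus obovatol and untreated cells from -0.11 to 0.13. For LPS against untreated cells 2 lists lay outside the central 95% of random lists, for LPS plus obovatol against LPS 3 did, and for LPS plus obovatol against untreated cells 2 did. Random lists would give 1.45 for each comparison.

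Rows listed under 1 gene did not share a level unless they were neighbours in the table. In 5469 listed genes with rows more than 500 places apart, taking 1 pair of rows for each gene, Spearman's correlation of the intensities was 0.014. Among 8098 pairs of adjacent rows of 1 listed gene it was 0.266, and among 19656 pairs of adjacent rows of different listed genes it was 0.267. Intensities followed the place in the table and not the listed gene. Between rows 31827 and 33137, 1311 rows held 1 row with an intensity over 2 times the background mode, against 29.5% of the whole table. In 1000 shuffled orders the longest such stretch had 55 rows. Of the 1287 listed olfactory receptor rows, 37 lay in this stretch, and 28.9% of the listed olfactory receptor rows were bright. The 500 brightest rows clustered as well. Rows 37209 to 37358 held 53 of them, against at most 11 in shuffled orders, and 0 of the listed ribosomal protein rows lay there. The authors' log2 table carried the same ID on the same values. For these reasons the following comparisons give numbers and sizes of changes and assign none to a gene.

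**Figure D1:**
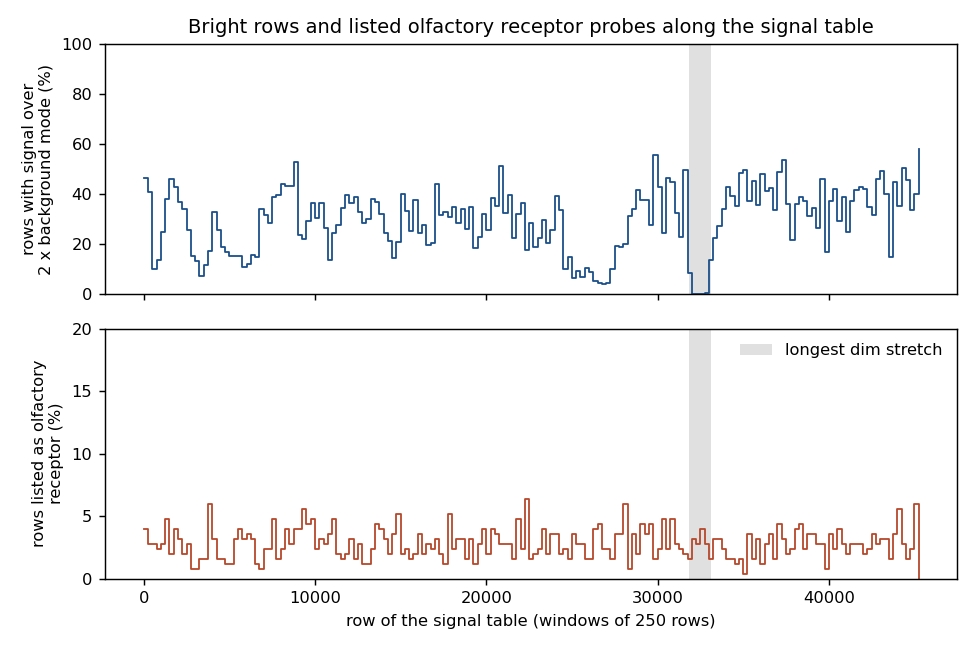
The upper panel plots the share of rows with a mean intensity over 2 times the background mode (percent) along the row number of the signal table, and the lower panel the share of rows listed as olfactory receptors (percent) in the same windows. The share of bright rows falls to near 0 in the shaded stretch of 1311 rows, while the 1287 listed olfactory receptor rows are spread over the whole table.

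LPS against untreated cells asks which transcripts LPS changed after 6 h, though no time is given for the untreated cells. Most of the changed rows were higher with LPS. Of 19652 rows detected in at least 1 of the 2 samples, 109 were at least 2-fold higher and 10 at least 2-fold lower. Of the higher rows, 37 reached 3-fold and 15 reached 4-fold, and 0 of the lower rows reached 3-fold. In all 109 higher rows both LPS arrays lay above both untreated arrays, and in 79 the difference was at least 2-fold for every pairing of arrays. Of the 10 lower rows, 9 had both LPS arrays below both untreated arrays and 2 were 2-fold lower in every pairing. The noise between arrays alone gave a median of 1 higher row in the simulation and at most 5, and a median of 1 lower row and at most 4.

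The largest increases with LPS were 11.9-fold at row 37406 and 11.6-fold at row 13865. Row 37406 had mean intensities of 184 in untreated cells, 1636 with LPS and 822 with LPS plus obovatol. Row 13865 had 112, 856 and 443. The largest decrease was at row 7607, with a log2 difference of -1.32 and intensities of 418, 138 and 300.1 in the same order. The next was a 2.28-fold decrease at row 16477, with 197, 78.1 and 73.8. The balance of higher and lower rows depended on the scaling. With median scaling in place of quantile normalization, which moved the median difference of the tested rows to -0.16, the counts were 74 higher and 38 lower. The first arrays alone gave 95 higher and 9 lower, and the second arrays alone 189 higher and 86 lower.

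LPS plus obovatol against LPS asks what obovatol changed in the presence of LPS. Of 19901 rows, 31 were at least 2-fold higher with obovatol and 35 at least 2-fold lower. The difference was at least 2-fold in every pairing of arrays for 15 of the higher and 17 of the lower rows. Simulated noise between arrays gave at most 4 rows in either direction. Of the 35 lower rows, 31 had been at least 2-fold higher with LPS than in untreated cells. With LPS plus obovatol, 28 of the 35 lay within 2-fold of untreated cells, including the 4 that were within 2-fold with LPS alone. The LPS arrays enter both the choice of these rows and their comparison with untreated cells. With rows chosen on 1 LPS array and read on the other, the part that was at least 2-fold higher with LPS ran from 87.0% to 95.8% of 23 or 24 rows with the first array of LPS plus obovatol, and from 32.8% to 57.4% of 120 or 122 rows with its second. Of the 31 higher rows, 27 were within 2-fold of untreated cells with LPS alone, and 18 were at least 2-fold above untreated cells with LPS plus obovatol. With median scaling, which moved the median of the tested rows to 0.11, 63 rows were higher and 22 lower. The first arrays alone gave 29 higher and 24 lower, and the second arrays alone 132 higher and 120 lower.

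The largest decrease with obovatol was 5.29-fold at row 11828, where the mean intensity was 181 in untreated cells, 482 with LPS and 122 with LPS plus obovatol. Row 11847 followed with 4.77-fold and intensities of 92.7, 269 and 76.7. The largest increase in the mean was 5.66-fold at row 20967, but the arrays differed there, with log2 differences from 1.22 to 3.78 over the pairings. Row 19074 followed with 3.41-fold and intensities of 945, 771 and 3082.

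The rows raised by LPS moved back towards the untreated level when obovatol was present. Of the 109 rows, 99 were lower with LPS plus obovatol than with LPS, and in 90 both arrays of LPS plus obovatol lay below both LPS arrays. The median log2 change of the 109 rows was 1.36 with LPS and -0.71 from LPS to LPS plus obovatol, with quartiles of -1.05 and -0.41. The median difference from untreated cells that was left was 0.68, and the median row retained 49.4% of its LPS change. At least 2-fold lower with obovatol were 31 rows, or 28.4% (exact binomial 95% interval 20.2% to 37.9%, which takes rows as independent and is too narrow where neighbouring rows change together). Still at least 2-fold above untreated cells were 36 rows, or 33.0%, and 2 rows rose at least 2-fold further with obovatol. The LPS arrays enter both differences with opposite signs, which by itself pulls the second below 0. In simulated unchanged samples a median of 1 row passed the threshold, and the median change of such rows ran from -0.91 to 0.54 over 100 runs, so the simulation gives no usable reference for the size of the fall. With rows chosen on 1 LPS array and measured against the other, the median over the choices of arrays lay between -0.52 and -0.23 with the first array of LPS plus obovatol and between -0.86 and -0.82 with its second. The share at least 2-fold lower lay between 11.5% and 42.1% over the 8 choices. Without this split, the first arrays alone gave a median of -0.58 and a share of 23.2%, and the second arrays alone -0.87 and 39.2%. Both LPS arrays are assigned to the same sample, so a deviation of that culture would stay in both differences.

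**Figure D2:**
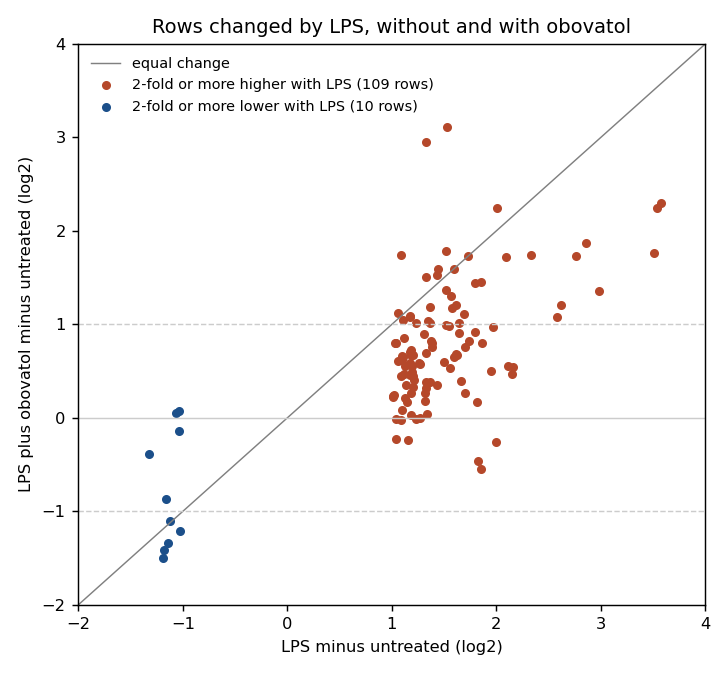
Each point is a probe row that differed at least 2-fold between LPS and untreated cells, with the log2 difference of LPS from untreated cells on the x axis and of LPS plus obovatol from untreated cells on the y axis (means of 2 arrays per sample). The solid diagonal marks an equal change and the dashed lines 2-fold. Of the 109 rows raised by LPS, 99 lie below the diagonal and 36 at or above the upper dashed line.

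Of the 10 rows lowered by LPS, 6 were higher with LPS plus obovatol than with LPS, 2 of them at least 2-fold, and the median change was 0.16 with quartiles of -0.20 and 0.93. With the authors' log2 values, which gave 6 such rows, the median was -0.086. It was positive in the other settings run, apart from 2 of the 8 choices of split arrays, at 0.42 for the 171 rows at least 1.5-fold lower, 0.59 for 38 rows with median scaling and 1.03 for 86 rows with the second arrays alone.

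LPS plus obovatol against untreated cells asks what remained changed under both agents. Of 19807 rows, 76 were at least 2-fold higher and 10 at least 2-fold lower. In every pairing of arrays 36 of the higher and 5 of the lower rows differed at least 2-fold. Simulated noise gave a median of 4 and at most 10 rows in either direction, so the 10 lower rows do not exceed it. The first arrays alone gave 72 higher and 11 lower, the second arrays alone 94 higher and 25 lower, and normexp with no offset 103 higher and 28 lower. The largest increase was 8.61-fold at row 39307, with mean intensities of 170.2 in untreated cells, 369 with LPS and 1281 with LPS plus obovatol. Row 39309, 2 places further on, followed with 7.71-fold. The largest decrease was 2.83-fold at row 16477, followed by 2.66-fold at row 22807.

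Higher than untreated cells in both LPS samples were 36 rows. Both comparisons use the same untreated arrays. Unchanged samples simulated against them shared a median of 1 row and at most 5, and independent lists of these sizes among the 19091 rows tested in both would share 0.43. With LPS set against the first untreated array and LPS plus obovatol against the second, 38 rows were higher in both, and with the arrays exchanged 31 were, where independent lists would share 0.51 and 0.63. The untreated arrays are assigned to 1 sample, so part of the excess may come from that shared sample.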

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

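The settings with first arrays alone, second arrays alone, a brightness filter, no offset, split LPS arrays and split untreated arrays were chosen after seeing the data. Recomputing the 9 main results under the alternatives gave 119 values, of which 81 stayed within their limits (1.5 times for a count, the spread between arrays for a median, the binomial interval for the share), 37 moved and 1 changed sign. The values are given in the order LPS against untreated, LPS plus obovatol against LPS, and LPS plus obovatol against untreated. The causes of the moves were not tested, except where the threshold itself sets the count. In place of 109, 31 and 76 rows higher and 10, 35 and 10 lower, a 1.5-fold threshold gave 343, 266 and 268 higher and 171, 198 and 150 lower, and a median change with obovatol of the rows raised by LPS of -0.41. A 3-fold threshold gave 37, 3 and 23 higher, 0, 8 and 0 lower, and a median of -0.99. With no background correction 20 rows were higher with obovatol than with LPS, and 4, 22 and 6 were lower. Normexp with an offset of 50 gave 19 higher and 4, 21 and 6 lower. With no offset 69 rows were higher with obovatol than with LPS, and 40, 60 and 28 were lower. Median scaling gave 38 rows lower with LPS than untreated, and 63 higher and 22 lower with obovatol than with LPS. The authors' log2 values gave 6 rows lower with LPS, and a median change of these with obovatol of -0.086 in place of 0.16, the only change of sign. The second arrays alone gave 189 rows higher and 86 lower with LPS, 132 higher and 120 lower with obovatol than with LPS, and 25 lower than untreated with both agents. They also gave a median of 1.03 for the rows lowered by LPS, and a share of rows moved back 2-fold of 39.2% in place of 28.4%. The median of the rows raised by LPS stayed below 0 in every setting run. A detection cut at 0.05 and no filter at all removed or added no changed row, so these 2 settings test nothing, and all their values count among the 81. The limit for a median came from the first-array and second-array results, which were themselves among the values judged. For the rows lowered by LPS these were 0.062 and 1.03, so the limit was wider than the main median of 0.16. A median of 0.59 with median scaling thus counted among the 81, which says little about the stability of that median. For the largest increase and decrease of each comparison, 36 values were recomputed, of which 30 stayed within the spread between arrays, 6 moved and 0 changed sign. The first-array and second-array values lay within this spread by construction, since the main value is their mean, so only their sign was a test.

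The mean over the probes of a gene, the selection on 1 probe with measurement on another probe of that gene, and the alternatives for gene lists and named genes were not run, since the gene names do not belong to the values. At a 3-fold threshold no row was lower with LPS, so that median has no value. No paired analysis was possible because each group has 1 sample. With 55.0% of the rows not detected in any sample, changes of dim rows are limited by the background.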

Other observations

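All tests in this part were chosen after the data had been examined. For a shifted annotation and for the smallest fall with split LPS arrays, the bounds were written before the test itself was run. No gene-level biology beyond the comparisons is given, since the gene names do not belong to the values.

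The mismatch between IDs and values has 4 explanations that were weighed. An annotation shifted along the table is argued against by a scan of all 45281 offsets, at which adjacent rows of 1 listed gene exceeded adjacent rows of different genes by at most 0.053 in Spearman correlation, while an annotation wrong in another way stays open. For poor RNA or weak hybridisation, the Spearman correlation of 0.014 between distant rows of 1 listed gene decides nothing, since it is part of the mismatch itself. Repeat arrays, whose lowest correlation was 0.990, argue against unsteady hybridisation but cannot speak to the quality of the RNA. Place in the table argues against poor RNA or weak hybridisation as the whole cause, since neither would sort intensities by row. The dim stretch of 1311 rows compares with at most 55 in shuffled orders. Of the 500 brightest rows, 53 lay within 150 adjacent rows, against at most 11. The quality of the RNA itself stays open. A candidate explanation is that the IDs and the values stand in different row orders, since the dim stretch of 1311 rows is close in length to the 1287 olfactory receptor probes of the platform, and a second dim stretch of 166 rows to its 157 vomeronasal type 1 receptor probes. The second stretch was searched for only in the part of the table well past the first, and its length was not set against shuffled orders. The values may follow an alphabetical order of gene symbols, in which ribosomal proteins would lie 38.8% of the way between the 2 families, and the brightest window lies at 40.0%. The absolute positions cannot be compared directly, since ranks leave out the 10378 rows with no symbol and the 18 with several. Among the rows with 1 symbol, olfactory receptors end at rank 21366 and vomeronasal type 1 receptors start at rank 32947. The first dim stretch ends at row 33137 and the second starts at row 43503. Fewer rows lie between them than symbols between the families, which goes against a plain order of these symbols. Whether an alphabetical order holds row by row, and where the orders parted, stays open, and no gene was named from it.

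Rows changed in a comparison also stood side by side. Of the 109 rows raised by LPS, 43 lay next to another, against at most 6 in shuffled orders. Of the rows that differed between LPS plus obovatol and LPS, 11 of the 31 higher and 14 of the 35 lower did so, against at most 2 in either case. The longest runs had 4 rows. The shuffled orders placed changed rows anywhere in the table, also among rows not detected, and ignored the clustering of bright rows. Their counts are therefore too low a reference, and the size of the excess is not known.

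The 2 arrays of a sample lay further apart for untreated cells and for LPS plus obovatol than for LPS. Independent noise of single arrays is argued against by a correlation across rows of 0.51 between the second-minus-first differences of these 2 samples, where that of either with the LPS sample was 0.0045 and -0.0030. A batch shared by these 2 second arrays may be the source, and it would raise the counts of the second arrays alone, which gave 120 rows lower with obovatol than with LPS in place of 35. The 1 biological replicate per group in the design text goes against another culture behind the second arrays. No label gives the origin of the RNA of each array, however, so the values cannot tell another culture from such a batch. The 45 rows that moved at least 2-fold the same way in both samples would follow from either. No biological explanation was tested.

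For the fall with obovatol of the rows raised by LPS, compression of bright values is argued against under median scaling, which leaves the shape of each array as it is, by 740 rows of the same LPS level that LPS had changed little, with a median change of 0.052 where the raised rows had -0.72. The shift of the second arrays as the whole cause is argued against by the choices without them, where the smaller fall was -0.51. The second array of LPS plus obovatol gave medians of -0.86 to -0.82 and its first array -0.52 to -0.23, so the shift may set much of the size, and a batch that sets all arrays of these 2 samples apart from LPS stays open. Noise of the LPS arrays as the whole cause is argued against by the split of these arrays, which left at least 77.2% of the fall found with the same arrays unsplit in each of the 8 choices. The limit for the share left was written after that result was known. With bounds written before the test, the smallest fall of -0.23 lay between -0.20 and -0.35. That test of the shared LPS arrays therefore did not decide. A deviation of the LPS culture, which would stay in both differences, cannot be told apart from an effect of obovatol. Such an effect remains a hypothesis.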
